A study of Mus musculus with 17 samples.

How the data were processed

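RNA sequencing was done on the choroid plexus of the lateral ventricles of C57BL/6 mice, per the labels. Total RNA was taken from the whole dissected tissue and made into libraries with the SMART-Seq v4 kit, which primes cDNA at the poly(A) tail and amplifies it by PCR for small amounts of RNA. The 17 libraries fall into a control group (CTRL, n = 5) and 3 groups given dextran sodium sulfate (DSS), a polymer that injures the colon lining and is used to induce colitis in mice. T1 had 1 day of DSS, T3 had 3 days, and T5 had 3 days of DSS and then 2 days of water (n = 4 each). Groups were taken from the time point label of each sample. Replicate numbers only name the samples, and the labels do not say that samples of a group came from separate animals. The p-values therefore measure the spread between these samples, which can be technical in part.

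The deposited values are raw read counts per Ensembl gene in one table for all 17 libraries. The submitters' processing notes name Trimmomatic 0.39, STAR 2.6.1b, featureCounts 1.6.4 and the mouse build GRCm38, without their order or settings. The annotation release, the strand setting and the handling of reads that match several genes are not given in the sources used here. Reads shared between near-identical genes (the globin genes, H2 class I genes, Tgtp2 and its copy) or between overlapping genes on opposite strands cannot be assigned with certainty, and PCR copies were counted as reads. Gene symbols and coordinates were taken from GENCODE release M21 on GRCm38, 1-based; 55394 of the 55487 gene identifiers in the table were found there and 93 were not.

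Library totals ran from 8875921 to 26839417 counts, with a median of 18004090. Of the 55487 genes, 39303 had at least 1 read and 16851 passed edgeR's filter on low counts (filterByExpr by group) and were tested. Detected genes were also counted after thinning every library to 8875921 counts. Libraries of a group differed by a chi-square of 8.11 to 121 per gene, and their log2 CPM correlated across genes with Pearson r of 0.917 to 0.981, so no library was counted as a copy of another.

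The tests, the comparisons, the gene lists and the rule for naming genes were fixed before the data were examined. Genes were tested with edgeR 4.0.16 in R 4.3.3: TMM normalization, a model with 1 mean per group over all 17 libraries, a robust quasi-likelihood fit and F tests, with Benjamini-Hochberg adjustment and a threshold of 0.05. All groups share the estimate of spread; the common dispersion was 0.141, a biological coefficient of variation of 37.6%. Values are given as TMM-normalised CPM (counts scaled to a common library size), mean ± SD over libraries, and log2 fold changes ± SE. For single genes edgeR returns no SE. It was taken as the absolute log2 fold change divided by the square root of edgeR's F, and is approximate. DESeq2 1.42.0, limma 3.58.1 (voom with sample quality weights) and sva 3.50.0 served as alternatives. The mean log2 CPM of each list per library was also compared with CTRL by two-sided exact permutation tests.

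The 37 gene lists held markers of choroid plexus epithelium, endothelium, mural cells, fibroblasts, border macrophages, microglia, neutrophils, monocytes and dendritic cells, lymphocytes, erythrocytes, neurons, astrocytes, oligodendrocytes and ependymal cells. They also held epithelial tight junctions, vascular barrier and endothelial junctions, Wnt beta-catenin targets, the type I interferon response, interferon gamma and antigen presentation, NF-kB with cytokine and acute phase genes, complement, immediate early genes, the glucocorticoid response, the circadian clock, heat shock, endoplasmic reticulum stress, hypoxia and glycolysis, cerebrospinal fluid secretion transporters, organic solute transporters, cilium and axoneme, cell cycle, extracellular matrix and basement membrane, the mitochondrial respiratory chain (nuclear), iron and metal handling, cholesterol synthesis, growth factors and hormones of the choroid plexus, and sex-linked genes. Each list was tested with limma's camera on log2 CPM (prior count 2) at a preset correlation of 0.01, adjusted over the 37 lists of a comparison, and again with an estimated correlation and with fry. Camera compares a list with the other genes; fry asks whether the members move, on balance, one way. Camera at the preset correlation treats members as nearly independent, and the estimated correlation lets members that vary together between libraries count for less.

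Genes were named by this rule: for each comparison with CTRL, the 8 largest rises and 8 largest falls among called genes with a mean of at least 1 CPM and a symbol that is not a predicted one, with all treated libraries on the same side of the control mean, and 4 and 4 for the other comparisons. Where no gene was called, the 10 with the smallest p were taken. Up to 4 members with the smallest p were added for each list described, and Plvap, Cdh5, Pecam1, Cldn1, Cldn2, Cldn3, Cldn5, Tjp1, Ocln, Ttr, Aqp1, Axin2 and Lcn2 in each comparison with CTRL.

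The pipeline was tested on simulated data drawn from the means and library sizes of these samples, with 100 genes changed 2-fold and 100 changed 4-fold. For T1 against CTRL, with 16368 genes tested, edgeR recovered 59% of the 2-fold and 88% of the 4-fold changes, and 6.83% of its calls were false. The corresponding shares were 60%, 92% and 1.28% for T3 (16405 genes) and 57%, 85% and 3.92% for T5 (16333 genes). DESeq2 called more of the 2-fold changes (71%, 67% and 65%, over 16849, 16847 and 16843 genes), with 22.6%, 18.8% and 21.3% of its calls false. Limma-voom with quality weights recovered 60%, 60% and 52% of them over the genes that edgeR tested, with 4%, 1.32% and 3.42% of its calls false. Simulated genes were drawn independently, so no difference in brain tissue or sample number was shared between them. The shares therefore do not measure how the tools perform on these libraries.

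The alternatives fixed beforehand were the other tools, relative log expression factors, library size without TMM, normalization without Ttr and mitochondrially encoded genes, no filter, a minimum of 1 CPM in 4 libraries, a fit of only the 2 groups compared, 1 surrogate variable, a brain marker covariate (neurons, astrocytes and oligodendrocytes), an erythrocyte marker covariate, an absolute log2 fold change of at least 1, and leaving out each library in turn. After the data were examined, a term for the 4 libraries with sample numbers of 28 and above in their titles was added, alone and with the brain marker covariate, as were separate neuron and oligodendrocyte covariates and a fit without these 4 libraries. No sample was left out of the main tests.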

Results

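Gene expression was measured by RNA sequencing in the choroid plexus, the vascularised epithelial tissue that secretes cerebrospinal fluid and forms a barrier between blood and that fluid. The tissue came from the lateral ventricles of C57BL/6 mice during and after dextran sodium sulfate (DSS), which induces colitis. Untreated controls (CTRL, n = 5) were compared with mice after 1 day of DSS (T1, n = 4), after 3 days (T3, n = 4), and after 3 days followed by 2 days of water (T5, n = 4). Library totals were 16021690 to 25854664 counts in CTRL, 8875921 to 23555242 in T1, 10881890 to 26839417 in T3 and 12477553 to 19928986 in T5. Ttr, the transthyretin gene of the choroid plexus epithelium, took 6.61 to 13.6% of the counts of a library.

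Libraries also differed in ways that cut across the groups. The sample titles carry running numbers, and 4 libraries have numbers of 28 and above: T1 replicates 2, 3 and 4 and T3 replicate 4. Thinned to 8875921 counts, these 4 had a mean of 25510 detected genes against 20730 in the other 13. The same 4 libraries had a lower share of mitochondrially encoded counts (1.98% against 2.995%) and a higher share of long non-coding and unconfirmed transcripts (1.06% against 0.736%). The set was singled out after these measures were seen, so no test of them is given. The labels name no batch. T1 replicate 1 is the only T1 library outside this set, so that this difference and the T1 group largely coincide. CTRL libraries have numbers of 1 to 8 and T5 libraries of 23 to 26, so sample number and group coincide fully in that comparison.

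Markers of neurons, astrocytes and oligodendrocytes, cells of the surrounding brain, varied widely within groups. The mean log2 CPM of the oligodendrocyte markers ran from 0.90 to 7.57 in CTRL and from 4.00 to 8.80 in T5. The first principal component of the 1000 most variable genes held 64.3% of the variance and followed the mean of these brain markers over the 17 libraries (Pearson r = 0.976, Spearman rho = 0.973, permutation p = 1e-05 for each, the smallest that the permutations can give). The brain markers were not taken out of the 1000 genes, so markers among them enter both measures. The permutation p does not allow for that. Without the 2 farthest libraries r was 0.964, and within the 13 libraries of lower sample number it was 0.981. This was the only correlation across samples computed.

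**Figure D1:**
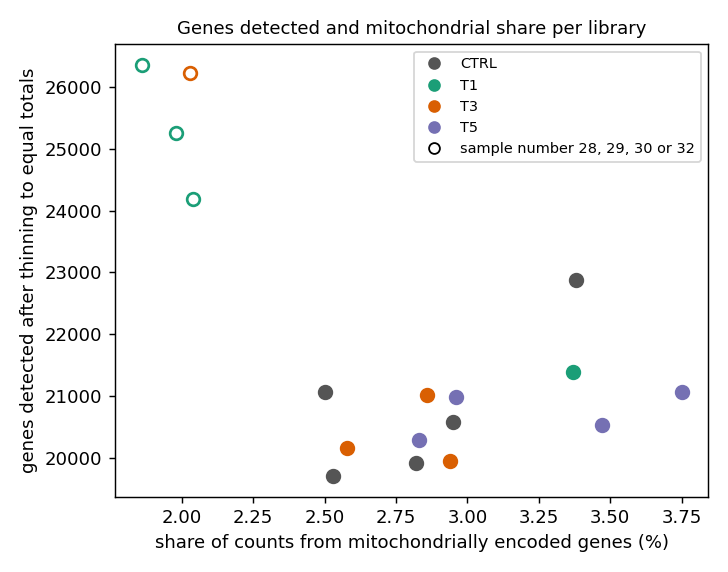
Share of counts from mitochondrially encoded genes (x axis, %) against the number of genes detected after thinning to 8875921 counts (y axis) in each of the 17 libraries, coloured by group; open symbols are the 4 libraries with sample numbers 28, 29, 30 and 32. The open symbols lie at 1.86 to 2.04% and 24194 to 26356 genes, the other libraries at 2.50 to 3.75% and 19706 to 22882 genes.

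After 1 day of DSS, the endothelium list rose: all 20 measured members had a positive log2 fold change, with a median of 1.06. Kdr, the main receptor for vascular endothelial growth factor on endothelial cells, stood at 76.5 ± 37.3 CPM in T1 (SD, n = 4) and 22.7 ± 3.95 CPM in CTRL (n = 5), a log2 fold change of 1.75 ± 0.33 (SE). Plvap, which forms the diaphragms of fenestrated capillaries, stood at 76.6 ± 37.7 CPM in T1 and 35.0 ± 11.1 CPM in CTRL, and Flt1 and Tek had log2 fold changes of 1.64 ± 0.46 and 1.49 ± 0.42. By edgeR, 11 members were higher when adjusted over the list alone, against 0 over all genes. For Kdr the edgeR adjusted p was 0.00166 over the list alone and 0.121 over all genes, and for Plvap 0.138 over all genes. Camera gave an adjusted p of 5.27e-07 for the list, and adjusted p = 0.741 with an estimated correlation. T1 replicate 1 lay apart from the other T1 libraries, at 24.5 CPM of Kdr and 33.0 CPM of Plvap against 83.9 to 113 and 65.4 to 123 CPM. Over its alternatives the median of the endothelium list ran from 0.11 to 1.3. With a term for the 4 libraries of high sample number the endothelium list had an adjusted p of 0.125. Without those libraries it had 0.108, in a fit with 1 T1 library that is assumed to vary like the other groups; over its 29 alternatives the adjusted p ran from 9.77e-09 to 0.125.

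Genes of the vessel wall and its matrix moved in the same direction at T1. The extracellular matrix and basement membrane list rose, with 28 of 30 members positive, a median log2 fold change of 0.70 and 8 members higher when adjusted over the list alone, against 0 over all genes. Its examples were Hspg2, which encodes perlecan (1.25 ± 0.28), the laminin genes Lama5 (0.94 ± 0.21) and Lamc1 (0.97 ± 0.26), and the basement membrane collagen gene Col4a2 (1.80 ± 0.50). The vascular barrier and endothelial junctions list rose as well (18 of 19 members positive, 5 higher when adjusted over the list alone and 0 over all genes), with Vwf, the von Willebrand factor gene, at 2.28 ± 0.76. The mural cells list rose too (11 of 12 positive, median 1.12, 0 members by either adjustment). Camera's adjusted p was 4.17e-05, 0.00239 and 0.0366 for these lists. All 3 had an adjusted p = 0.741 with an estimated correlation. With the term for high sample numbers they stood at 0.84, 0.505 and 0.529. Without those 4 libraries, with the 1 T1 library left assumed to vary like the other groups, they stood at 0.531, 0.108 and 0.846; over their alternatives the adjusted p ran from 7.12e-06 to 0.869, 0.000617 to 0.505 and 0.0153 to 0.846. The median of the vascular barrier and endothelial junctions list ran from 0.06 to 0.69 over its alternatives. With the term the medians of the extracellular matrix and mural cells lists turned to -0.02 and -0.53, and with the term and the brain marker covariate to -0.04 and -0.61. The mean log2 CPM of T1 replicate 1 was 4.76 and 2.45 for these 2 lists, against 5.49 to 5.64 and 3 to 3.47 in the other T1 libraries and 6.11 and 4.4 in T3 replicate 4. The mural cells list also lost its call without CTRL replicate 3 (0.0965), CTRL replicate 5 (0.11), T1 replicate 3 (0.0698), T1 replicate 4 (0.0795) or T5 replicate 2 (0.054).

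Genes of energy metabolism were lower at T1. All 30 members of the mitochondrial respiratory chain (nuclear) list had a negative log2 fold change, with a median of -0.50, and 18 were lower when adjusted over the list alone, against 0 over all genes. Uqcrc1, a subunit of complex III, stood at 426 ± 76.9 CPM in T1 and 599 ± 61.7 CPM in CTRL (-0.49 ± 0.14), and Ndufs3 and Cox5a had log2 fold changes of -0.59 ± 0.18 and -0.56 ± 0.17. In the hypoxia and glycolysis list 6 members were lower when adjusted over the list alone and 0 over all genes, among them the glycolytic genes Tpi1 (-0.49 ± 0.13) and Aldoa (-0.48 ± 0.13), and 8 of the 21 members had a positive sign. The heat shock list fell too (14 of 16 members negative, median -0.23, 0 members by either adjustment). In mean log2 CPM the respiratory chain list stood at 8.77 in T1 replicate 1, within the 8.65 to 8.94 of CTRL. It stood at 7.82 to 8.35 in the other T1 libraries and 7.99 in T3 replicate 4, the libraries with the lower mitochondrial and higher long non-coding shares. Its median was -0.77 without T1 replicate 1, 0.02 with the term for high sample numbers and -0.03 without those 4 libraries, where T1 has 1 library. Camera gave adjusted p of 1.69e-13, 0.0321 and 0.00513 for these lists. Each had an adjusted p = 0.741 with an estimated correlation. With the term for high sample numbers they stood at 0.599, 0.447 and 0.599; over their alternatives the adjusted p ran from 1.77e-21 to 0.865, 0.000497 to 0.447 and 4.42e-05 to 0.962. The heat shock list also lost its call without CTRL replicate 3 (0.0538) or T1 replicate 4 (0.0518).

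Immediate early genes and inflammatory genes were higher at T1, unevenly between libraries. Of the immediate early genes list 20 of 21 members were positive, with a median of 1.08 and 7 members higher when adjusted over the list alone, against 0 over all genes. Fos stood at 16.1 ± 15.7 CPM in T1 against 2.39 ± 1.23 in CTRL (2.75 ± 0.83). Ccn1 had a log2 fold change of 2.13 ± 0.63 and Zfp36, which promotes decay of cytokine mRNA, 1.13 ± 0.31. In the NF-kB, cytokine and acute phase list 28 of 30 members were positive and 6 were higher when adjusted over the list alone (0 over all genes). Lrg1 had 2.34 ± 0.58, the metalloreductase gene Steap4 1.78 ± 0.53, Ccl2, a chemokine for monocytes, 2.41 ± 0.77 and Osmr, the oncostatin M receptor gene, 1.48 ± 0.36. Osmr reached 26.4 CPM in T1 replicate 3 and 9.37 to 10.1 CPM in the other T1 libraries. Ccl2 reached 8.29 CPM in T1 replicate 3 and 0.51 to 0.774 CPM in the others. Lcn2, an acute phase gene, stood at 49.2 CPM in T1 replicate 3 and 0.182 to 0.918 CPM in the other T1 libraries (adjusted p = 0.147). Camera gave adjusted p of 7.33e-05 and 0.00239 for the 2 lists, and both had an adjusted p = 0.741 with an estimated correlation. The NF-kB, cytokine and acute phase list had an adjusted p of 0.33 without T1 replicate 3 and 0.559 with the term for high sample numbers, and the immediate early genes list 0.799 with that term, where its median turned to -0.03. Without those 4 libraries, with 1 T1 library, the medians of the 2 lists were -0.13 and -0.19; over their alternatives the adjusted p ran from 0.000112 to 0.962 and from 2.43e-05 to 0.981.

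Clock genes differed at T1 without a shift of the whole list. Arntl (Bmal1), the activator at the centre of the circadian clock, stood at 31.1 ± 9.68 CPM in T1 and 14.8 ± 2.96 CPM in CTRL, a log2 fold change of 1.07 ± 0.20, and its partner Npas2 had 0.79 ± 0.23. Dbp, a clock output gene, was lower, at 14.5 ± 5.63 against 33.3 ± 7.44 CPM (-1.19 ± 0.23). These 3 members passed when adjusted over the list alone (0.000839 for Arntl and Dbp, 0.019 for Npas2), and 0 did over all genes (0.121 for Arntl and Dbp). T1 replicate 1, which lies outside the 4 libraries of high sample number, had the highest Arntl of its group (40.0 CPM) and the lowest Dbp (8.67 CPM). The circadian clock list had 9 of 18 members positive and a camera adjusted p of 0.747. The labels give no hour of dissection.

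Other lists past camera at T1 were neurons (median 1.86, adjusted p = 7.33e-05), complement (0.51, 0.0221), the glucocorticoid response (0.53, 0.0218) and border macrophages (0.31, 0.0366), all higher. With an estimated correlation their adjusted p was 0.741, 0.741, 0.741 and 0.856 in that order. Complement lost its call without CTRL replicate 3 (0.0538), T1 replicate 1 (0.138) or T1 replicate 3 (0.145), the glucocorticoid response without T1 replicate 4 (0.121), and border macrophages without CTRL replicate 2 (0.081), CTRL replicate 3 (0.195), T1 replicate 1 (0.136), T1 replicate 3 (0.426) or T5 replicate 2 (0.0543). Over the alternatives the adjusted p ran from 2.44e-05 to 0.95 for neurons, 0.00241 to 0.145 for complement, 0.00205 to 0.865 for the glucocorticoid response and 0.000678 to 0.761 for border macrophages. Slc17a7, a glutamate transporter gene of neurons, stood at 15.6 ± 6.96 CPM in T1 and 1.6 ± 1.39 CPM in CTRL. In all, 10 lists rose and 3 fell of 37; none was called with an estimated correlation or with fry. Junction genes of the epithelium named beforehand did not pass the test. Cldn1 had a log2 fold change of 0.22 ± 0.17, Cldn2 of -0.03 ± 0.18, Cldn3 of -0.30 ± 0.19, Tjp1 of 0.59 ± 0.31 and Ocln of 0.16 ± 0.16. The epithelial tight junctions list had a camera adjusted p of 0.754.

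Over all genes, edgeR called 0 genes between T1 and CTRL, with 3553 of 16851 at an unadjusted p under 0.05 (1589 higher, 1964 lower; 843 expected by chance) and a lowest adjusted p of 0.121. DESeq2 called 496 genes (235 higher, 261 lower) and limma-voom with quality weights 4084. Without T1 replicate 1 edgeR called 2203 genes and without T3 replicate 4, a library of neither group that enters the shared estimate of spread, it called 717. The genes with the smallest p were Prpsap2 (-0.58 ± 0.10), Gga3 (0.95 ± 0.18), Arntl, the predicted gene Gm47283 (1.49 ± 0.28), Otub1 (-0.48 ± 0.09), Tra2a (0.60 ± 0.11), Mecr (-0.65 ± 0.13), Creb3l2 (0.71 ± 0.14), Tamm41 (-0.80 ± 0.16) and Aspscr1 (-0.58 ± 0.11). In 1139 genes (6.76%) the T1 and CTRL values did not overlap, against 1.59% by chance. Kdr lies on chromosome 5 (75932827 to 75978458, minus strand), Plvap on chromosome 8 (71497765 to 71511752, minus strand), Arntl on chromosome 7 (113207465 to 113314126, plus strand) and Dbp on chromosome 7 (45705088 to 45710203, plus strand); all 4 are annotated as protein-coding.

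**Figure D2:**
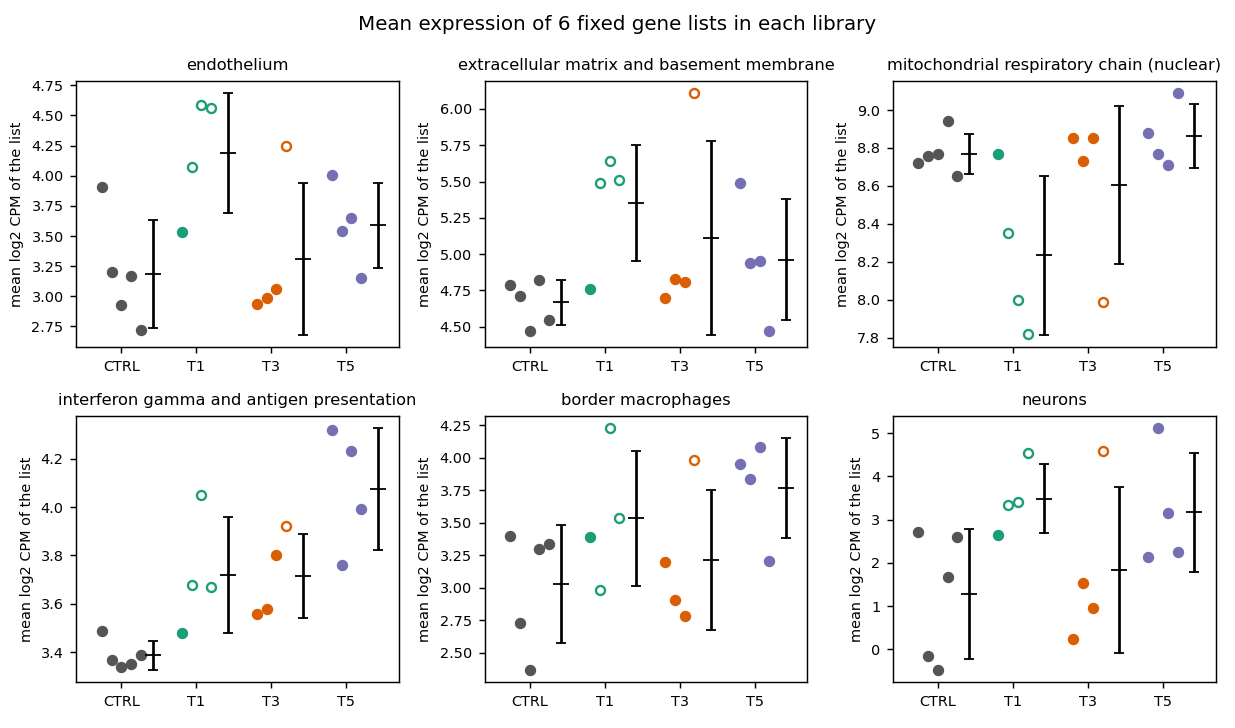
Mean log2 CPM of the members of 6 gene lists in each library (y axis) by group (x axis); open symbols are the 4 libraries with sample numbers of 28 and above, and the bars are the mean ± SD of each group (n = 5 for CTRL, 4 for the others). The interferon gamma and antigen presentation list lies at 3.34 to 3.49 in CTRL and 3.76 to 4.32 in T5; the endothelium list lies at 3.53 to 4.59 in T1, with T1 replicate 1 lowest.

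After 3 days of DSS, the clock genes stayed apart from CTRL and genes of ependymal cells, the ciliated lining of the ventricles, were lower. Arntl stood at 31.6 ± 5.51 CPM in T3 (n = 4) and 14.8 ± 2.96 CPM in CTRL (n = 5), a log2 fold change of 1.10 ± 0.20, and Dbp at 15.6 ± 3.83 against 33.3 ± 7.44 CPM (-1.08 ± 0.23). Arntl, Dbp and Npas2 (0.69 ± 0.23) passed when adjusted over the circadian clock list alone (0.00063, 0.00201 and 0.047), and 0 members did over all genes; the list itself had a camera adjusted p of 0.978. All 12 ependymal cells markers had a negative log2 fold change, with a median of -0.42. Spag17, a protein of the ciliary central pair, fell by 1.80 ± 0.46 and Foxj1, the main transcription factor of motile cilia, by 0.54 ± 0.16; these 2 passed when adjusted over the list alone (0.0125 and 0.0259), and 0 did over all genes. Camera gave the ependymal cells list an adjusted p of 2.81e-07, with adjusted p = 0.326 with an estimated correlation, and the call held at the preset correlation in all 29 alternatives (2.47e-09 to 0.00129). The median of the ependymal cells list was -0.24 without T3 replicate 4. In mean log2 CPM T3 replicates 1 and 2 stood at 4.35 and 4.27, within the 4.1 to 4.93 of CTRL. Only T3 replicates 3 and 4 lay below that range, at 3.72 and 3.35.

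The interferon gamma and antigen presentation list rose slightly at T3: 24 of 27 members were positive, with a median of 0.25 and a camera adjusted p of 0.00148 (adjusted p = 0.695 with an estimated correlation); 0 members passed when adjusted over the list alone or over all genes. Iigp1, an interferon-induced GTPase, stood at 5.21 ± 2.10 CPM in T3 and 2.83 ± 0.88 CPM in CTRL (0.89 ± 0.37, unadjusted p = 0.027 by edgeR). The type I interferon response list had a median of 0.15 and an adjusted p of 0.324. At T1 the interferon gamma and antigen presentation list was not called, but its median was 0.35, with 19 of 27 members positive. Its camera adjusted p at T1 was 0.095 (0.835 with an estimated correlation). In mean log2 CPM the list lay 0.3348 above CTRL at T1 and 0.3265 at T3, so these values do not place a start of the rise at T3.

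The calls of fibroblast and matrix genes at T3 rested on 1 library. The fibroblasts list (13 of 15 members positive, median 0.48) and the extracellular matrix and basement membrane list (29 of 30 positive, median 0.36) had camera adjusted p of 0.00187 and 3.05e-05, and adjusted p = 0.695 for both with an estimated correlation. Without T3 replicate 4 they stood at 0.18 and 0.149; over their alternatives the adjusted p ran from 5.42e-07 to 0.206 and from 4.28e-07 to 0.206. Fn1, the fibronectin gene, stood at 145 CPM in T3 replicate 4 and 2.31 to 13 CPM in the other T3 libraries, and Col1a2 at 263 against 72.3 to 98.0 CPM. Plvap stood at 22.9 ± 4.36 CPM in T3 against 35.0 ± 11.1 CPM in CTRL (-0.62 ± 0.35, adjusted p = 0.911), and the endothelium list had a median of 0.16 and an adjusted p of 0.476.

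The other lists past camera at T3 had medians of at most 0.30, apart from erythrocytes (-0.64, adjusted p = 0.00812) and oligodendrocytes (-2.58, 0.0113), both lower. Their adjusted p was 0.77 and 0.801 with an estimated correlation. Hbb-bs, a beta globin gene, stood at 312 ± 65.2 CPM in T3 and 504 ± 192 CPM in CTRL. Higher lists were endoplasmic reticulum stress (0.00187), organic solute transporters (0.0019), growth factors and hormones of the choroid plexus (0.02), Wnt beta-catenin targets (0.0278) and cerebrospinal fluid secretion transporters (0.0481); the mitochondrial respiratory chain (nuclear) list (0.00187) and the cilium and axoneme list (0.00937) were lower. With an estimated correlation the adjusted p was 0.77 for endoplasmic reticulum stress, 0.695 for organic solute transporters, growth factors and Wnt beta-catenin targets, 0.801 for cerebrospinal fluid secretion transporters, 0.844 for the respiratory chain and 0.77 for cilium and axoneme. Calls ended without T3 replicate 4 for the respiratory chain (0.402, median 0.03), cilium and axoneme (0.569), Wnt beta-catenin targets (0.417) and growth factors (0.0719). Leaving out T3 replicate 3 ended those of endoplasmic reticulum stress (0.0942), growth factors (0.0788), oligodendrocytes (0.0788), Wnt beta-catenin targets (0.0537) and cerebrospinal fluid secretion transporters (0.19). Without CTRL replicate 1, organic solute transporters (0.149), growth factors (0.0721), oligodendrocytes (0.126) and cerebrospinal fluid secretion transporters (0.58) were not called. Other single libraries ended the calls of erythrocytes (CTRL replicate 4 and T3 replicate 2, 0.0565 each), oligodendrocytes (CTRL replicate 5, 0.334; T3 replicate 1, 0.0526), Wnt beta-catenin targets (CTRL replicates 2 and 4, 0.0531 and 0.0675) and cerebrospinal fluid secretion transporters (T3 replicates 1 and 2, 0.0958 and 0.192; T5 replicates 1, 3 and 4, 0.0587, 0.0551 and 0.0527). Over the alternatives the adjusted p ran from 1.14e-05 to 0.23 for erythrocytes, 1.11e-05 to 0.891 for oligodendrocytes, 5.92e-08 to 0.0942 for endoplasmic reticulum stress, 0.000337 to 0.149 for organic solute transporters, 0.00206 to 0.0876 for growth factors, 0.0054 to 0.505 for Wnt beta-catenin targets, 0.00113 to 0.58 for cerebrospinal fluid secretion transporters, 1.31e-05 to 0.807 for the respiratory chain and 9.27e-05 to 0.813 for cilium and axoneme.

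EdgeR called 0 genes between T3 and CTRL, with 838 at an unadjusted p under 0.05 (539 higher, 299 lower; 843 expected by chance) and a lowest adjusted p of 0.59. DESeq2 called 1, Arntl (adjusted p = 0.0067), and limma-voom with quality weights 0. After Arntl and Dbp, the smallest p belonged to Arhgdig (-0.60 ± 0.14), Creb3l2 (0.55 ± 0.14), Spag17, Comp (3.37 ± 0.86), Rapgef1 (-0.70 ± 0.18), Twsg1 (0.47 ± 0.12), Gna12 (-0.99 ± 0.25) and Cmtm6 (0.56 ± 0.15). T3 and CTRL values did not overlap in 287 genes (1.7%, chance 1.59%). Ttr and the junction genes Cldn1, Cldn2, Cldn3, Ocln and Tjp1 had adjusted p of 0.911 or more; these 5 junction genes had log2 fold changes between -0.20 ± 0.19 for Cldn3 and 0.40 ± 0.31 for Tjp1.

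After 3 days of DSS and 2 days of water, interferon gamma and antigen presentation genes rose together: all 27 members were positive, with a median log2 fold change of 0.73, and 13 were higher when adjusted over the list alone, against 0 over all genes. Iigp1 stood at 8.25 ± 3.93 CPM in T5 (n = 4) and 2.83 ± 0.88 CPM in CTRL (n = 5), a log2 fold change of 1.55 ± 0.37. Cxcl10, an interferon-induced chemokine that attracts T cells, had 2.58 ± 0.64. H2-Ab1, a chain of the MHC class II molecule, stood at 78.2 ± 21.9 against 43.1 ± 11.8 CPM (0.86 ± 0.22), and H2-D1, a class I gene, had 0.73 ± 0.19. Their p adjusted over the list alone was 0.00903 for Iigp1, Cxcl10 and H2-Ab1 and 0.00925 for H2-D1. Camera gave the list an adjusted p of 1.66e-14 (adjusted p = 0.0514 with an estimated correlation) and fry 0.0104. The camera call held in all 29 alternatives at the preset correlation (6.96e-21 to 2.26e-09), while the median went down to 0.47 with the erythrocyte marker covariate. The mean log2 CPM of the list was above every CTRL library in 4 of 4 T5 libraries (exact permutation p = 0.00794, the smallest that 126 splits allow, and 0.0979 adjusted over the 37 lists). At T5 the NF-kB, cytokine and acute phase list and the sex-linked genes had the same p by this test. So did this list at T3 and the growth factors and hormones list at T1. No list passed once adjusted, with a lowest adjusted p of 0.122 at T1, 0.294 at T3 and 0.0979 at T5. Border macrophages at T5 had an adjusted p of 0.157, cilium and axoneme at T5 0.339 and ependymal cells at T3 0.514.

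Markers of border macrophages, the resident macrophages of the choroid plexus and meninges, rose at T5: 18 of 19 members were positive, with a median of 0.77, and 8 were higher when adjusted over the list alone, against 0 over all genes. C1qb, a chain of complement C1q, stood at 89.0 ± 31.5 CPM in T5 and 48.2 ± 10.7 CPM in CTRL (0.89 ± 0.26), and the signalling adaptor genes Tyrobp and Fcer1g had 0.86 ± 0.23 and 0.81 ± 0.25. Microglia express these 3 genes as well, and 9 of 9 members of the microglia list were positive (median 0.64), among them Tmem119 with 1.07 ± 0.35 and P2ry12 with 0.81 ± 0.60. That list had a camera adjusted p of 0.00546 (adjusted p = 0.459 with an estimated correlation; 0.000125 to 0.963 over the alternatives), so the markers do not separate the 2 cell types. The type I interferon response list rose in 26 of 28 members (median 0.57), with Irf7 at 1.01 ± 0.30, Ifit3 at 1.51 ± 0.49 and Isg15 at 1.38 ± 0.50, and 0 members passed when adjusted over the list alone or over all genes. For border macrophages and the type I interferon response camera gave adjusted p of 3.42e-09 and 2.72e-06. With an estimated correlation the adjusted p was 0.348 and 0.459. Both calls held in all 29 alternatives at the preset correlation (8.47e-13 to 0.00165 and 1.82e-10 to 0.00582), with smaller medians in some. With the erythrocyte marker covariate the median was 0.27 for border macrophages and 0.29 for the type I interferon response, and the term for high sample numbers with the brain marker covariate gave 0.49 for border macrophages.

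Most genes of the cilium and axoneme list and the sex-linked genes were lower at T5. In the cilium and axoneme list 19 of 24 members were negative, with a median of -0.16 and 2 lower when adjusted over the list alone (0 over all genes). Cfap44 fell from 63.5 ± 5.63 to 40.4 ± 9.61 CPM (-0.65 ± 0.15) and Cfap43 had -0.47 ± 0.12, both genes of ciliary axoneme proteins. Dnah9, a dynein of motile cilia, and Ift88 had -0.52 ± 0.17 and -0.37 ± 0.13. In mean log2 CPM the cilium and axoneme list stood at 4.26 in T5 replicate 2 and 4.54 in T5 replicate 1. T5 replicates 3 and 4 stood at 4.76 and 4.75, within the 4.58 to 4.85 of CTRL. The ependymal cells list, which shares members with it, did not fall at T5 (7 of 12 positive, median 0.04, camera adjusted p = 0.354). All 5 sex-linked genes had a negative log2 fold change; Eif2s3y (-0.83 ± 0.26) and Kdm5d (-0.48 ± 0.18), both on the Y chromosome, passed when adjusted over the list alone (0.0239 and 0.0484), and 0 did over all genes. Camera gave adjusted p of 4.24e-05 and 0.000706, and with an estimated correlation adjusted p = 0.348 and 0.238. With separate neuron and oligodendrocyte covariates the cilium and axoneme list had an adjusted p of 0.392, the highest of its alternatives (lowest 4.92e-06); the sex-linked genes kept their call in all 29 (0.000126 to 0.0131), with medians of -0.69 to -0.32.

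Markers of neurons and astrocytes were higher at T5 too. All 14 neurons markers were positive, with a median of 2.06, and Nefm, a neurofilament gene, was higher when adjusted over the list alone (0.0228), against 0 over all genes. The excess was uneven: Slc17a7 reached 92.4 CPM in T5 replicate 2 and 1.97 to 7.66 CPM in the other T5 libraries. The neurons and astrocytes lists had camera adjusted p of 7.9e-07 and 0.00121, both with adjusted p = 0.459 with an estimated correlation. Over the alternatives the adjusted p of astrocytes ran from 7.29e-05 to 0.389, and the call ended with 1 surrogate variable (0.302), the erythrocyte marker covariate (0.108) and separate neuron and oligodendrocyte covariates (0.274). The neurons markers were called in each fit that left out 1 library. Their adjusted p was 0.0548 with 1 surrogate variable (lowest 1.11e-09). The separate covariates contain the neuron markers (0.876 for neurons) and the brain marker covariate the astrocyte markers (0.257 for astrocytes, 0.389 with the term), so these values follow from how the covariates were built and do not test the calls. The oligodendrocytes list had an adjusted p of 0.095.

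The other lists past camera at T5 were all higher. They were erythrocytes (median 0.74, adjusted p = 0.000706), fibroblasts (0.62, 0.000552), microglia (0.64, 0.00546), lymphocytes (0.65, 0.0329), endothelium (0.35, 0.00529), vascular barrier and endothelial junctions (0.29, 0.0411), immediate early genes (0.71, 0.000233), complement (0.52, 0.00069), the glucocorticoid response (0.37, 0.00204), NF-kB with cytokine and acute phase genes (0.23, 0.00235), endoplasmic reticulum stress (0.17, 0.00275), cell cycle (0.23, 0.0105), heat shock (0.13, 0.0411) and growth factors and hormones of the choroid plexus (0.10, 0.0411). With an estimated correlation their adjusted p lay between 0.348 for complement and lymphocytes and 0.648 for heat shock. Over the alternatives the adjusted p ran from 4.93e-05 to 0.843 for erythrocytes, 6.12e-06 to 0.236 for fibroblasts, 0.000125 to 0.963 for microglia, 0.000717 to 0.137 for lymphocytes, 9.69e-05 to 0.724 for endothelium, 0.00571 to 0.822 for the vascular barrier, 7.66e-06 to 0.747 for immediate early genes, 6.84e-06 to 0.0983 for complement, 0.000142 to 0.45 for the glucocorticoid response, 0.000213 to 0.101 for NF-kB, 1.3e-06 to 0.0911 for endoplasmic reticulum stress, 0.000949 to 0.196 for cell cycle, 8.32e-06 to 0.299 for heat shock and 0.00375 to 0.365 for growth factors. Without T5 replicate 1 the calls of endothelium (0.114), vascular barrier and endothelial junctions (0.299), lymphocytes (0.0777) and growth factors (0.365) ended. Without T5 replicate 3 those of microglia (0.2), cell cycle (0.0805), heat shock (0.0533) and vascular barrier and endothelial junctions (0.0658) did, and without T5 replicate 4 those of endoplasmic reticulum stress (0.081) and heat shock (0.272). Control libraries ended calls as well. CTRL replicate 1 ended those of endoplasmic reticulum stress (0.0911), heat shock (0.299) and growth factors (0.215), and CTRL replicate 5 those of endothelium (0.131), lymphocytes (0.0728), heat shock (0.179) and vascular barrier and endothelial junctions (0.179). CTRL replicate 2 ended that of heat shock (0.137) and CTRL replicates 3 and 4 that of vascular barrier and endothelial junctions (0.067 and 0.0614), which T1 replicate 1 brought to 0.05. Plvap had a log2 fold change of 0.07 ± 0.34, Cldn2 of 0.02 ± 0.18, Cldn5 of 1.17 ± 0.67 and Lcn2 of 2.15 ± 1.29 (adjusted p = 0.726).

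EdgeR called 0 genes between T5 and CTRL, with 1320 at an unadjusted p under 0.05 (656 higher, 664 lower; 843 expected by chance) and a lowest adjusted p of 0.521. DESeq2 called 17 (5 higher, 12 lower), among them Cxcl10, Iigp1, Nefm and Cfap44, and limma-voom with quality weights 0. The smallest p belonged to Ddi1 (-4.34 ± 0.81), the dynein gene Dnah7b (-0.84 ± 0.17), Gm43605 (-3.07 ± 0.62), Dnmbp (-0.59 ± 0.12), AC104328.1 (-1.86 ± 0.40), Gm48887 (-4.36 ± 0.95), the interferon-induced GTPase gene Tgtp2 (1.68 ± 0.37), Rmst (-1.35 ± 0.30), Gm37019 (-2.11 ± 0.47) and Cfap44. T5 and CTRL values did not overlap in 431 genes (2.56%, chance 1.59%). H2-Ab1 lies on chromosome 17 (34257689 to 34269419, plus strand), Iigp1 on chromosome 18 (60376027 to 60392634, plus strand) and Cxcl10 on chromosome 5 (92346638 to 92348889, minus strand); all 3 are protein-coding.

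**Figure D3:**
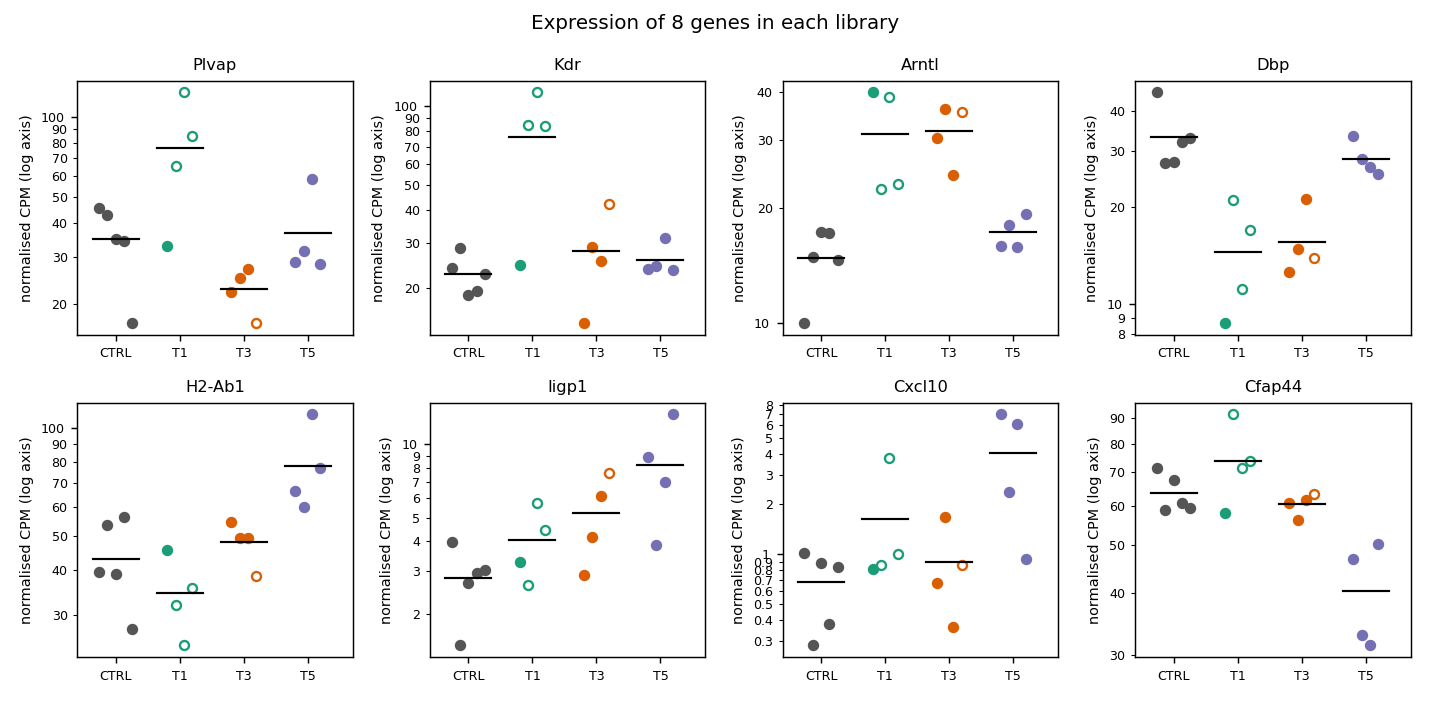
TMM-normalised CPM (y axis, log scale) of 8 genes in each library by group (x axis); open symbols are the 4 libraries with sample numbers of 28 and above, and lines are group means. Arntl is at 22.4 to 40.0 CPM in T1 and 24.3 to 36.1 CPM in T3 against 9.99 to 17.3 CPM in CTRL, and H2-Ab1 is at 60.1 to 109 CPM in T5 against 27.4 to 56.2 CPM in CTRL.

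Between T1 and T3, Plvap had one of the 10 smallest p, and no gene passed the test over all genes. Plvap stood at 22.9 ± 4.36 CPM in T3 and 76.6 ± 37.7 CPM in T1 (-1.74 ± 0.37, adjusted p = 0.476 by edgeR), lower in 4 of 4 T3 libraries than in each T1 library, T3 replicate 4 included (17 CPM). Gpihbp1, a protein of capillary endothelium that holds lipoprotein lipase, had -1.31 ± 0.29 and Ramp3, a receptor activity-modifying protein, -1.48 ± 0.28. Spag17 (-2.48 ± 0.48), Rapgef1 (-1.04 ± 0.19), Gm47283 (-1.75 ± 0.31), Ripply3 (-2.24 ± 0.44), Exoc3l2 (-2.72 ± 0.61), Tra2a (-0.54 ± 0.12) and Nif3l1 (0.60 ± 0.13) completed the 10 smallest p. EdgeR called 0 genes, with 1381 at an unadjusted p under 0.05 (601 higher, 780 lower; 843 expected) and a lowest adjusted p of 0.297; DESeq2 called 26, Plvap among them (adjusted p = 0.00174), and limma-voom with quality weights 4065. EdgeR called 3 genes without T1 replicate 2 (Rapgef1, Sppl3 and Gna12) and 3 without T3 replicate 4 (Pno1, Adgrf5 and Malat1); Sppl3, Pno1, Adgrf5 and Malat1 are named after their values were seen. Values did not overlap in 451 genes (2.68%, chance 2.86%).

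Between T3 and T5, blood, macrophage and interferon genes were higher after the 2 days of water. The erythrocytes list rose in 7 of 7 members (median 1.31), with Hbb-bs at 873 ± 281 CPM in T5 and 312 ± 65.2 CPM in T3 (1.49 ± 0.37), and 5 members were higher when adjusted over the list alone, against 0 over all genes. Of the border macrophages list 16 of 19 were positive and 6 higher when adjusted over the list alone (0 over all genes), with C1qb at 1.08 ± 0.28, C1qa at 1.03 ± 0.30 and Tyrobp at 1.01 ± 0.25. Of the microglia list 8 of 9 were positive, with a median of 0.77 and a camera adjusted p of 0.0318 (adjusted p = 0.663 with an estimated correlation; 0.00192 to 0.93 over the alternatives). Of the interferon gamma and antigen presentation list 20 of 27 were positive and 7 higher when adjusted over the list alone (0 over all genes), with the immunoproteasome genes Psmb8 and Psmb9 at 1.07 ± 0.31 and 0.93 ± 0.31 and Cxcl10 at 2.17 ± 0.68. For erythrocytes, border macrophages and interferon gamma camera gave adjusted p of 9.71e-06, 4.23e-05 and 0.000217. With an estimated correlation they had adjusted p = 0.484, 0.651 and 0.484. The erythrocyte marker covariate took the border macrophages list to 0.999 and the brain marker covariate took it to 0.0702 (lowest of its alternatives 2.38e-08), while the interferon gamma and antigen presentation list was called in all 29 alternatives (3.37e-07 to 0.0375), with medians of 0.23 (erythrocyte marker covariate) to 0.49.

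Arntl was lower and Dbp and the ependymal cells list were higher in T5 than in T3. These comparisons and those of T3 with CTRL use the same T3 libraries, so opposite signs arise in part without any change. Arntl stood at 17.2 ± 1.70 CPM in T5 and 31.6 ± 5.51 CPM in T3 (-0.88 ± 0.21) and Dbp at 28.5 ± 3.57 against 15.6 ± 3.83 CPM (0.86 ± 0.24). Both passed when adjusted over the circadian clock list alone (0.0115 and 0.0215), 0 did over all genes, and the list had a camera adjusted p of 0.434. Against CTRL, T5 had log2 fold changes of 0.22 ± 0.20 for Arntl and -0.22 ± 0.23 for Dbp (edgeR adjusted p = 0.85 and 0.873). The ependymal cells list rose (10 of 12 positive, median 0.42, camera adjusted p = 0.00328), with adjusted p = 0.569 with an estimated correlation and 0.102 without T3 replicate 4 (lowest of its alternatives 4.46e-05). Spag17 had 1.95 ± 0.47 and was the only member higher when adjusted over the list alone (0.00872), against 0 over all genes.

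The iron and metal handling list rose between T3 and T5 (11 of 17 positive, camera adjusted p = 0.0318, adjusted p = 0.512 with an estimated correlation). The metallothionein genes Mt1 and Mt2, which bind zinc and copper, had 1.13 ± 0.23 and 1.99 ± 0.61 and passed when adjusted over the list alone (0.0022 and 0.0409), against 0 over all genes; the list lost its call without T3 replicate 3 (0.0703), T3 replicate 4 (0.0648) or T5 replicate 3 (0.0634). Camera also called higher lists of oligodendrocytes (adjusted p = 0.00128), neurons (0.00328), astrocytes (0.0175), microglia (0.0318), type I interferon response (0.00299), heat shock (0.00721), glucocorticoid response (0.0318), mitochondrial respiratory chain (nuclear) (0.000904) and lymphocytes (0.013). Their adjusted p with an estimated correlation lay between 0.431 for lymphocytes and 0.707 for the respiratory chain. Lower lists were choroid plexus epithelium (0.0318), epithelial tight junctions (0.0318), cerebrospinal fluid secretion transporters (0.0318), organic solute transporters (0.013), extracellular matrix and basement membrane (0.0413) and sex-linked genes (0.0044). With an estimated correlation the adjusted p of the lower lists lay between 0.468 for sex-linked genes and 0.707 for choroid plexus epithelium and the extracellular matrix. The choroid plexus epithelium list had a median of -0.16, and without 1 of T3 replicates 1, 2 and 3 or T5 replicates 2 and 3 its adjusted p was 0.129, 0.176, 0.207, 0.247 and 0.129. The same 5 libraries ended the calls of the epithelial tight junctions (0.058, 0.0846, 0.0968, 0.126 and 0.0634), the cerebrospinal fluid secretion transporters (0.0663, 0.117, 0.125, 0.18 and 0.0575), astrocytes (0.0691, 0.0624, 0.0641, 0.0833 and 0.0971) and microglia (0.058, 0.0707, 0.176, 0.106 and 0.348). Without T3 replicate 4 the respiratory chain, the extracellular matrix and heat shock stood at 0.838, 0.895 (median 0.23) and 0.195. Other single libraries ended calls of neurons (T3 replicate 1, 0.0691; T5 replicate 2, 0.122, median -0.18), oligodendrocytes (T5 replicate 3, 0.0634), type I interferon response (T3 replicate 1, 0.0812), organic solute transporters (T5 replicate 2, 0.0833), lymphocytes (T3 replicate 3, 0.0569; T5 replicate 2, 0.0641), heat shock (T5 replicate 4, 0.0545), glucocorticoid response (T3 replicates 1 and 3, 0.0691 and 0.243; T5 replicates 2 and 3, 0.0833 and 0.076) and extracellular matrix and basement membrane (CTRL replicate 4, 0.0513; T5 replicates 2, 3 and 4, 0.126, 0.0575 and 0.434). Over the alternatives the adjusted p ran from 6.49e-06 to 0.945 for oligodendrocytes, 2.2e-07 to 0.854 for neurons, 0.00036 to 1 for astrocytes, 0.00192 to 0.93 for microglia, 5.35e-06 to 0.68 for type I interferon, 3.51e-05 to 0.249 for heat shock, 0.00152 to 0.713 for the glucocorticoid response, 9.87e-15 to 0.838 for the respiratory chain, 0.00782 to 0.179 for lymphocytes, 0.000104 to 0.907 for choroid plexus epithelium, 0.00579 to 0.713 for tight junctions, 0.00176 to 0.796 for secretion transporters, 0.0034 to 0.19 for organic solute transporters, 0.000272 to 0.99 for the extracellular matrix, 0.00166 to 0.0677 for sex-linked genes and 0.00462 to 0.0757 for iron and metal handling.

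EdgeR called 0 genes between T5 and T3, with 1764 at an unadjusted p under 0.05 (727 higher, 1037 lower; 843 expected) and a lowest adjusted p of 0.267. DESeq2 called 47, limma-voom with quality weights 0, and edgeR with 1 surrogate variable 361; without T5 replicate 4 edgeR called 1, Slit2. The smallest p belonged to Ddi1 (-4.32 ± 0.83), Bc1 (1.70 ± 0.33), Arhgdig (0.76 ± 0.15), Mt1, AC104328.1 (-1.99 ± 0.41), Dnmbp (-0.62 ± 0.13), Gm19409 (-2.65 ± 0.57), the axon guidance gene Slit2 (-1.19 ± 0.26), Rhou (2.04 ± 0.44) and Kmt5a (0.54 ± 0.12). Values did not overlap in 1240 genes (7.36%, chance 2.86%).

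Between T1 and T5, single genes passed the threshold: edgeR called 677, of which 208 were higher and 469 lower in T5 (4352 at an unadjusted p under 0.05, 843 expected; lowest adjusted p 0.0189). The largest rises by the naming rule were Bc1, a short neuronal non-coding RNA (10.4 ± 2.25 CPM in T5 and 2.96 ± 1.13 CPM in T1; 1.82 ± 0.33, adjusted p = 0.0189), the fatty acid binding protein gene Fabp3 (1.19 ± 0.31, 0.0442) and the class II genes H2-Ab1 (1.18 ± 0.23, 0.0198) and H2-Aa (1.09 ± 0.28, 0.0406). The largest falls were Pde6b (-3.49 ± 0.66, 0.0189) and Rpgrip1 (-3.29 ± 0.87, 0.0443), genes of photoreceptors, the collagen gene Col7a1 (-3.16 ± 0.86, 0.0479) and the long non-coding RNA gene Lncpint (2.14 ± 0.73 against 14.6 ± 6.23 CPM; -2.77 ± 0.49, 0.0189). Pde6b stood at 8.56 CPM in T1 replicate 4 and 1.73 to 2.73 CPM in the other T1 libraries, and Rpgrip1 at 5.83 and 0.51 to 1.3 CPM. Genes lower in T5 were long, with a median exon length of 7099 bases, against 2272.5 for those higher in T5 and 4091 for all tested genes. Values did not overlap in 2053 genes (12.2%, chance 2.86%). Bc1 lies on chromosome 7 (144914470 to 144914637, plus strand) and Lncpint on chromosome 6 (31082565 to 31220488, minus strand), both annotated as lincRNA.

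The number of calls depended on the settings and on single libraries. EdgeR called 0 genes with the term for the libraries of high sample number, 0 without them and 0 with the erythrocyte marker covariate. The median absolute log2 fold change of the 677 genes was 0.79 (median SE 0.19). It was 0.45 (0.20) with the term, 0.44 (0.24) without the 4 libraries and 0.76 (0.21) with the erythrocyte marker covariate. Of the 677, 677 kept their sign in the first and last of these fits, and 657 of 676 in the fit without the 4 libraries, where T1 has 1 library. Lncpint stood at 14.9 to 21.6 CPM in T1 replicates 2 to 4 and 16.2 CPM in T3 replicate 4, against 6.43 CPM in T1 replicate 1 and 2.71 to 7.85 CPM in the other T3 and CTRL libraries. DESeq2 called 1910 genes and limma-voom 3730. Leaving out 1 library gave 0 calls without T1 replicate 2, T1 replicate 3 or T5 replicate 3, 1 (Brinp1, named after its value was seen) without T5 replicate 2, 22 without T5 replicate 1, 200 without T1 replicate 4 and 381 without T5 replicate 4. It gave 435 to 450 without CTRL replicate 2 or 3, 438 without T3 replicate 1, 2184 without T3 replicate 4 and 3169 without T1 replicate 1. All 677 calls were also called by DESeq2.

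Over the 4 groups together, edgeR's F test called 0 genes, with 3034 at an unadjusted p under 0.05 (843 expected) and a lowest adjusted p of 0.103; DESeq2 called 852 and limma-voom with quality weights 3829. Without T1 replicate 1 edgeR called 1222 and without T3 replicate 4 it called 454. No gene was called by edgeR at 2 times against CTRL, since each comparison had 0 calls. At an unadjusted p under 0.05, T1 and T3 shared 368 genes with the same sign, against 85.7 for independent lists and 137.4 for simulated unchanged groups with the same controls. T1 and T5 shared 170 (139.2 and 133.7) and T3 and T5 shared 119 (32.8 and 132.9). With the controls split into 3 and 2 libraries, these numbers were 83 to 92, 14 to 26 and 10 to 11. The covariance of the log2 fold changes was 0.18, 0.18 and 0.167 for the 3 pairs, against 0.0967, 0.0965 and 0.0971 simulated from the shared controls, a difference of 0.0836, 0.0836 and 0.0695. Their correlation across genes was 0.532, 0.426 and 0.471, against 0.433, 0.433 and 0.438 simulated. The simulation held no changed genes, so its shared counts do not allow for the 3553 genes of T1 at an unadjusted p under 0.05. T1 and T3 both hold libraries of high sample number, so their overlap does not separate time from sample number. The cholesterol synthesis, neutrophils and monocytes and dendritic cells lists had camera adjusted p of 0.179, 0.44 and 0.434 for T1 against CTRL, 0.343, 0.35 and 0.359 for T3 against CTRL, 0.761, 0.366 and 0.43 for T5 against CTRL, and 0.68, 0.958 and 0.929 for T5 against T3.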

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

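The tests chosen after the result was seen were the term for the 4 libraries of high sample number for the endothelial, Plvap and interferon gamma results, the models of mean log2 CPM with the brain marker covariate for the endothelial and interferon gamma results and with the erythrocyte covariate for the latter, and the other splits of the samples for T1 and T3 against CTRL. The edgeR fits with the brain marker and erythrocyte covariates were fixed beforehand. The tests of border macrophages, of T5 against T1 and the other splits for the remaining comparisons were written down beforehand. The differences between T5 and T1 were taken up because 677 genes changed differently from CTRL in these groups by edgeR's test of the difference. Single libraries are listed where 1 lay far from the rest of its group, which chance alone gives in about 1 of 20 groups of normally distributed values. CPM of single genes were not log-transformed for this rule, so the rate need not hold for them.

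Endothelial markers were higher in T1, by 1 ± 0.33 (SE) in mean log2 CPM of the endothelium list. Brain tissue in the dissection is argued against as the whole cause, since the T1 difference was 0.75 ± 0.32 with the brain marker covariate. The difference between the 4 libraries of high sample number and the others may account for it: with a term for these libraries the T1 difference was 0.20 ± 0.31 and the term itself 1.07 ± 0.28. For Plvap, which stood at 17 CPM in T3 replicate 4, the T1 difference with the term was 0.72 ± 0.52 and the term 0.44 ± 0.46, so that for Plvap the time and the sample number cannot be told apart with 1 T1 library outside the set. An effect of 1 day of DSS on vessels stays open as a hypothesis.

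Interferon gamma and antigen presentation genes were higher in T5, by 0.69 ± 0.13 in mean log2 CPM. The difference was 0.64 ± 0.14 with the brain marker covariate, 0.53 ± 0.13 with the border macrophage covariate and 0.61 ± 0.14 with the erythrocyte covariate, which argue against brain tissue, border macrophages or blood as the whole cause. Part of it may still come with blood, since the median log2 fold change of the list's genes went from 0.73 to 0.47 with the erythrocyte covariate. No covariate for lymphocytes, microglia or dendritic cells was fitted, so a change in these cells was not tested. The lymphocyte markers had a mean log2 CPM of 0.86 to 1.19 in T5 and 0.17 to 0.80 in CTRL. None of the 4 libraries of high sample number is in T5 or CTRL, so the term for them could not move the difference (0.69 with it) and tests nothing. Sample numbers ran from 1 to 8 in CTRL and from 23 to 26 in T5. Anything that follows the sample number therefore cannot be told apart from T5 here. A response of the tissue to interferon after DSS stays open as a hypothesis found and tested on the same data, with an adjusted p of 0.0514 with an estimated correlation (6.96e-21 to 2.26e-09 over the 29 alternatives at the preset one).

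Between T5 and T1, 677 genes were called, and 1 of 35 splits of the 8 libraries, the real one, gave as many (highest other 17). This is the smallest share that 35 splits allow, and it was not adjusted for the other comparisons, so chance is less likely but not excluded. The splits do not separate time from sample number either. The 4 other splits that kept T1 replicates 2 to 4 together had 2434 to 4124 genes at an unadjusted p under 0.05 (4352 for the real split, at most 1945 for the rest). Sample number may contribute: on a scale from T5 (0) to the other T1 libraries (1), T1 replicate 1 had a median place of 0.51 (quartiles 0.32 and 0.74) over these genes, and T3 replicate 4 lay on the T1 side of the other T3 libraries in 92.9%. The 677 genes were called with T1 replicate 1 counted in T1, which by itself moves its place away from T5. The place lies near the middle, and time and sample number cannot be told apart with 1 T1 library of low number. With the trend of transcript length and GC content removed, 369 genes were called and 288 of the 677 remained (42.5%), while for the 389 calls that ended the median absolute log2 fold change went from 0.70 to 0.42 and the median SE from 0.17 to 0.14. Such a trend and the groups cannot be told apart here, since a real change in long genes would be removed with it.

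Counts of splits include the real one. As many genes at an unadjusted p under 0.05 came from 4 of 100 splits for T1 against CTRL (3553 genes, highest other 4463). For T3 they came from 34 of 100 (838, highest other 2372) and for T5 from 12 of 100 (1320, highest other 2253). The T1 share was small, but other splits gave larger counts, and the shares were not adjusted for the number of comparisons. Chance is therefore not excluded at any of these times. The 3 other splits as large for T1 (4142, 4436 and 4463) all kept its 3 libraries of high sample number together, and splits that parted them gave at most 1690. The count therefore does not separate time from sample number. For T3 against T1 the count was 9 of 35 (1381, highest 7191) and for T5 against T3 4 of 35 (1764, highest 3051), so chance is not excluded. The split of T1 and T3 that sets the 4 libraries of high sample number against the others gave the 7191, with 4995 past the adjusted threshold, which points to a structure of the samples. Over the 4 groups 2 of 100 splits gave as many (3034, highest 3480), the real one among them. The share was small, but it was not adjusted either and another split gave more, so chance is not excluded. The split with 3480 had 539 past the adjusted threshold, against 0 for the real one, which points to a structure of the samples as well. The count over the 4 groups does not separate time from sample number, since the real groups had 1546 with the term for high sample numbers and 1814 without the 4 libraries. For the number of gene lists past camera, 38 of 100 splits gave as many for T1 (13 lists, highest 21), 45 of 100 for T3 (13, highest 23), 9 of 100 for T5 (21, highest 26) and 5 of 35 for T5 against T3 (20, highest 23), so chance is not excluded for these numbers of lists.

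Of 470 groups of values, 56 had a library far from the rest, 24 of them T3 replicate 4. In mean log2 CPM, T3 replicate 4 was high for endothelium (4.25, others 2.94 to 3.06), mural cells (4.4, 1.81 to 2.23), fibroblasts (6.95, 5.22 to 5.48), astrocytes (6.13, 3.7 to 3.88), the vascular barrier (4.94, 3.95 to 4.03), complement (4.84, 4.08 to 4.20), the circadian clock (4.70, 4.26 to 4.30) and extracellular matrix (6.11, 4.70 to 4.83). It was low for choroid plexus epithelium (9.95, others 10.3 to 10.4) and the respiratory chain (7.99, 8.73 to 8.85). Thinned to 8875921 counts in all, it had about 26200 detected genes. In CPM it stood apart for Comp (11), Pecam1 (40.5), Tjp1 (61.7), Lcn2 (3.38), Rhou (4.78), Fn1 (145), Col1a2 (263), Col6a2 (66.4), Mog (7.95), Mbp (491), Gbp4 (9.11), Nefm (12.1) and Camk2a (43.5).

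T1 replicate 3 was high for Lcn2 (49.2 CPM, other T1 libraries 0.182 to 0.918), Ccl2 (8.29, 0.51 to 0.774), Osmr (26.4, 9.37 to 10.1), Exoc3l2 (20.2, 3.38 to 5.19) and the iron and metal handling list (6.02 in mean log2 CPM, 5.4 to 5.45). T1 replicate 1 had 3.37% of mitochondrially encoded counts (others 1.86 to 2.04%), a mean of 4.12 for the circadian clock (4.57 to 4.64) and of 4.76 for extracellular matrix (5.49 to 5.64). T1 replicate 4 stood apart for Axin2 (3.82 CPM, others 5.71 to 6.03), Pde6b (8.56, 1.73 to 2.73) and Rpgrip1 (5.83, 0.51 to 1.3), and T1 replicate 2 for Nif3l1 (17.6, 15.8 to 16).

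T5 replicate 2 was high for the neuronal genes Slc17a7 (92.4 CPM, other T5 libraries 1.97 to 7.66), Nefm (25, 4.01 to 5.89) and Camk2a (174, 1.6 to 14.8). T5 replicate 3 was high for the myelin genes Mog (201, 5.81 to 12.7) and Opalin (106, 3.94 to 5.82), for Plvap (58.4, 28.3 to 31.7) and for Rhou (26.5, 7.97 to 11.1). T5 replicate 1 was high for Cldn5 (45.6, 7.21 to 11.3) and Fabp3 (65.2, 42.7 to 46.1), and T5 replicate 4 had 0.0582 CPM of Gm48887 where the others had 0. CTRL replicate 1 had 0.947% of long non-coding and unconfirmed transcripts (others 0.711 to 0.773%), means of 9.78 for choroid plexus epithelium, 6.48 for endoplasmic reticulum stress and 4.46 for cholesterol synthesis, and 4.97 CPM of Cdh5, 17.2 of Rapgef1 and 16.2 of Rmst. CTRL replicate 4 stood at 47.7 CPM of Mecr (33.3 to 36.6), CTRL replicate 5 at 2.02 of Lcn2 (0.336 to 0.645) and T3 replicate 1 at 7.51 of Rapgef1 (9.23 to 9.5).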

How the results depend on the processing

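The term for high sample numbers, alone or with the brain marker covariate, the separate neuron and oligodendrocyte covariates and the fit without the 4 libraries were chosen after seeing the data; the other alternatives were fixed beforehand. Where a value moved, the cause was not tested. No paired analysis was possible because the replicate numbers follow accession order and only name the samples. Of 11368 values of named genes, 11017 kept their side of the threshold, 110 lost a call and 241 gained one. The main test called genes only between T5 and T1, so all 110 losses fell on the genes named there. Most of the 11017 values had no call to lose and do not measure how firm the calls were. Among named genes 155 values without a call changed sign, and 0 called values did. For 66 list results that camera called, of 2046 values 1612 kept their side and 434 lost a call. Among these lists 32 values without a call changed sign, and 0 called values did. The interferon gamma and antigen presentation list at T5 is described on its own below and is not among the 66. Lists without a call gained one in 153 of 2511 values. At T5 the median of microglia went to -0.02 with the term and the brain covariate, and between T3 and T5 that of border macrophages to -0.04 with the erythrocyte covariate and that of choroid plexus epithelium to 0.03 with the surrogate variable. A covariate built from a list's own markers takes up its difference by construction, so the fits of neurons, astrocytes, oligodendrocytes and erythrocytes with their own covariates test nothing.

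For genes changed, DESeq2 gave 496 for T1 against CTRL, 1 for T3, 17 for T5, 26 for T3 against T1, 47 for T5 against T3, 1910 for T5 against T1 and 852 over the 4 groups, and limma-voom with quality weights 4084 (T1), 4065 (T3 against T1), 3730 (T5 against T1) and 3829 (4 groups). The surrogate variable gave 361 for T5 against T3, 2738 for T5 against T1 and 1048 over the groups, and no filter 10 over the groups. For T5 against T1 the 677 became 1336 (370 higher, 966 lower) with library size only, which shifted the median of all genes to -0.188; the same scaling gave medians of 0.21 for T1 against CTRL and -0.121 for T3 against T1. They became 355 without the filter, 42 with only these groups (fewer samples), 2341 with the brain marker covariate, 1778 with separate neuron and oligodendrocyte covariates, 233 at an absolute log2 fold change of at least 1, and 0 with the erythrocyte covariate, with the term for high sample numbers (alone or with the brain covariate) and without the 4 libraries. Leaving out 1 library gave 0 to 2203 for T1 against CTRL, 0 to 3 for T3 against T1, 0 to 1 for T5 against T3, 0 to 3169 for T5 against T1 and 0 to 1222 over the groups.

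The lists past camera, 13 for T1, 13 for T3, 21 for T5 and 20 for T5 against T3, became 0 in each with an estimated correlation, and 0, 0, 1 and 1 with fry. The interferon gamma and antigen presentation list at T5 kept its median of 0.73 but had an adjusted p of 0.0514 with an estimated correlation. For T1, 0 of the 13 were called with the term for high sample numbers, alone or with the brain covariate. In both fits 4 other lists were called: choroid plexus epithelium, endoplasmic reticulum stress, cerebrospinal fluid secretion transporters and organic solute transporters. For T5 the surrogate variable gave 11, and the erythrocyte covariate and the separate neuron and oligodendrocyte covariates 13 each. For T5 against T3 these gave 10, 7 and 10, the brain covariate 9 and the term with the brain covariate 13. Leaving out 1 library gave 9 to 15 lists for T1, 9 to 16 for T3, 18 to 24 for T5 and 10 to 21 for T5 against T3. Totals of 8875921 to 26839417 counts limit what can be seen of genes near 1 CPM.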

Other observations

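The lymphocyte markers that could be tested, 6 of the 14 on the list, were all higher in T5 than in T3, with a median log2 fold change of 0.82. Their expression was low, with a mean log2 CPM of 0.86 to 1.19 in T5 and -0.19 to 0.70 in T3. Ighm, the immunoglobulin M heavy chain gene, had a log2 fold change of 1.05, and Nkg7, a granule protein gene of cytotoxic lymphocytes, of 1.34. Camera gave an adjusted p of 0.013 (adjusted p = 0.431 with an estimated correlation) and fry 0.027; 0 members passed in edgeR when adjusted over the list alone or over all genes. Without T3 replicate 3 the camera value was 0.0569 and without T5 replicate 2 it was 0.0641, within a range of 0.00782 to 0.179 over the alternatives.

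T1 replicate 3 held transcripts of pituitary hormones, chosen after their values were seen: Gh, the growth hormone gene, had 57779 reads (4170 CPM of the library total, 0 to 23.1 in the other libraries), Prl, the prolactin gene, 4159 reads, and Pomc 1283 reads (92.5 CPM of the library total, 0.346 to 2.51 in the others). The same library held the highest Lcn2, at 49.2 CPM. No explanation of these values was tested.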
